A study of Mus musculus with 2 samples.

How the data were processed

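H3K4me2, dimethylation of lysine 4 on histone H3 and a mark of active and poised promoters and enhancers, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse hearts at embryonic day 13.5. Per the labels, the tissue came from the B6NCrl strain, male and female embryos were pooled, and fragments of 300 to 500 bp were sequenced. The labels give 1 group with 2 biological replicates from separate biosamples, so the design holds no contrast between conditions. The comparisons made here are replicate against replicate, and peak positions against the annotated genome.

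The 4 deposited peak lists are on mm10, which is the GRCm38 build. Per the deposited notes, each replicate's list was called on that replicate's alignments with 1 control file, and the pooled list on both replicates' alignments with 2 control files. The replicated list was derived from both replicate lists and the pooled list, per the same deposited notes. The aligner, the peak caller, the replication rule and the read depth of each library are not given in the sources used here. For each peak the authors deposited a signal value, which follows the narrowPeak column order and whose scale is not stated. The deposited lists also give −log10 p and −log10 q for each peak, and the offset of the summit. Signal values, p and q are the authors' own and were used only to rank, filter or describe peaks within a list. Every deposited −log10 p was above 2, as a p limit of 0.01 leaves. Alignments and signal tracks were not analysed here.

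Peaks of a replicate with −log10 q of at least 2 are called strict below. The replicated list was used as deposited. Overlap between lists meant at least 1 shared bp, and chance overlap came from 100 random placements of the other list's peaks on the same chromosomes. Spearman's rho of peak signal was taken across pooled peaks overlapped in both deposited replicate lists; such peaks are not independent replicates. Genes were taken from GENCODE release M21 and sequence from the GRCm38 reference, the same build as the peaks. Each peak was placed by its summit, in the order promoter (within 1 kb of a transcription start site, TSS, of a protein-coding gene), exon, intron and intergenic. A gene had a promoter peak when a replicated peak overlapped the window 1 kb either side of the 5′ end of its annotated gene record.

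The value of a gene was the length covered by strict peaks within 10 kb either side of that 5′ end, out of a possible 20 kb, as the mean ± SD over 2 replicates. For each of 18 gene lists the median over genes was set against 10000 random lists of as many protein-coding genes, matched on the decile of observed over expected CpG within 500 bp of the TSS. A list's median was taken over the genes' means of 2 replicates. The SD beside it is that of the medians of the 2 replicates. Both replicate medians can lie on the same side of the printed median, so this SD is not a spread around it. A list was said to stand apart when its median lay outside the central 95% of the random medians. These percentiles describe these libraries and are not p-values, and no p-values are given, since 1 group of 2 replicates offers no test between conditions. Replicated peaks at most 1 kb apart were stitched into domains. Consensus motifs were searched on both strands in 500 bp around the summits of distal replicated peaks, those over 5 kb from every annotated TSS, and in windows 5 kb to either side that overlapped no pooled peak. Intervals on shares are exact (Clopper-Pearson, 95%), and those on ratios of shares use a normal approximation on the log scale. Both cover counting error only, since neighbouring genes and peaks are not independent.

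Genes were named by a fixed rule. From each list the up to 4 genes with the largest mean covered length and the up to 2 with the smallest were eligible, and 10 and 4 from the cardiac transcription factors. Also eligible were the 10 protein-coding genes with the largest covered length and those in the 10 widest domains. Other named genes are said to have been chosen after their values were seen. The groups, lists, motifs, thresholds, naming rule and alternative settings were chosen before the data were examined. The alternatives varied the peak threshold, the overlap rule, the promoter window, the matching of random lists, the gene window, the stitching gap, the motif window and background, and left out each replicate in turn.

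Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used, with bedtools 2.31.1 as a check and matplotlib 3.10.9 for plots. On simulated data for the gene list comparison, run on 21938 genes, 5.5% of null lists of 25 genes fell outside the limits. Lists with 1 kb added to each gene were found in 44.5% of cases, and those with 5 kb added in 100%. The genes of these lists were drawn at random and matched on random bins, not on CpG deciles. The rates therefore do not cover the CpG matching, lists of CpG-poor genes or lists of neighbouring genes. The count of overlapped peaks equalled that of bedtools, with a difference of 0. For the motif search, all 500 planted GATA sites were found.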

Results

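H3K4me2 was profiled in the hearts of mouse embryos at day 13.5, a stage at which the chambers have formed and the valves and the conduction system are maturing. Replicate 1 had 69940 deposited peaks and replicate 2 had 66949, or 68445 ± 2115 (SD, n = 2). The strict lists held 65598 and 62239 peaks, which covered 72.3 and 67.1 Mb. Of 73700 pooled peaks, 54828 (74.4%) were in the authors' replicated list, with the same start, end and signal value. These replicated peaks had a median width of 914 bp and covered 76.9 Mb, 2.82% of the genome. The other pooled peaks were narrower, with a median of 253 bp, and their median signal was 2.52 against 6.98. Of the replicated peaks, 92.7% were overlapped in both replicate lists.

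The first comparison asks how far the 2 replicates mark the same regions. Of the strict peaks of replicate 1, 79.0% (interval 78.7 to 79.3) were overlapped by a strict peak of replicate 2, and 87.5% (87.3 to 87.8) the other way round. Randomly placed peaks overlapped 5.29% and 5.56%. Signal ranks across 50923 pooled peaks overlapped in both lists had a Spearman's rho of 0.916. Covered length around 21938 protein-coding genes had a rho of 0.991 between replicates, across genes. Only 3 peaks had identical coordinates in both lists, and none of these had an identical signal.

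Peaks called in 1 replicate only were mostly away from promoters. Promoters held 7.33 ± 0.811% of strict peaks with no overlap in the other deposited list, against 32.5 ± 0.392% of shared peaks (SD, n = 2). Their median width was 249 ± 8.13 bp against 798 ± 53.7 bp. They made up 18.5% of the strict peaks of replicate 1 and 10.8% of those of replicate 2.

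Blood cell genes, above all those of red cells, were more covered in replicate 1 than in replicate 2. The list of 20 blood cell genes had a median of 4.19 kb in replicate 1 and 2.03 kb in replicate 2. Hba-a1, an adult alpha globin on chromosome 11, was covered over 14.1 and 10.7 kb, and Slc4a1, the red cell anion exchanger band 3, over 16.4 and 13.5 kb. Hba-a2 was covered over 11.9 and 8.91 kb, and Hba-x, the embryonic zeta globin, over 11.5 and 8.46 kb. The windows of these globin genes overlap one another. Of the 20 genes, 17 were higher in replicate 1 and 0 in replicate 2. Genes leaned this way in general, with 11610 of 21938 higher in replicate 1 and 4886 in replicate 2. Cell cycle genes split 17 to 1, so the size of the difference, not the count, set the blood list apart. Over all protein-coding genes the difference had a median of 0.025 kb and a mean of 0.148 kb. Against random lists matched on covered length, a comparison added after these values were seen, the median difference of the blood list lay at percentile 100. Of the other 17 lists, 2 also lay outside the central 95%, the epicardial, valve and fibroblast list above (0.503 kb) and the sarcomere list below (0.025 kb). Cx3cr1 and Fcer1g, markers of myeloid cells, were at 0 kb in both replicates.

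**Figure D1:**
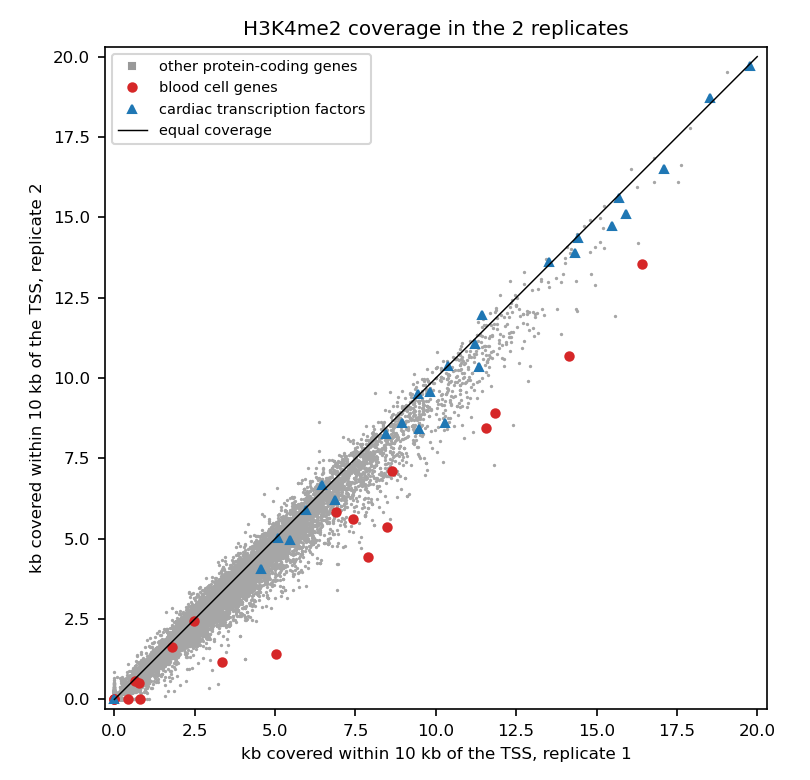
Length in kb covered by strict H3K4me2 peaks within 10 kb of the TSS in replicate 1 (x axis) and replicate 2 (y axis), 1 point per protein-coding gene; the line marks equal coverage. Most genes lie near the line. More covered in replicate 1 were 17 of 20 blood cell genes (red circles) and 11610 of all 21938 protein-coding genes.

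The next comparison asks where in the genome the mark lay. Promoters of protein-coding genes held 16718 replicated peaks, 30.5% of the list, while they take up 3.59% of the assembled chromosomes, an 8.48-fold excess. In the strict lists the share was 28.8 ± 1.59% (SD, n = 2). Promoter peaks were broad, with a median of 2198 bp, and held 52.6% of all bp covered. Introns held 37.2% of the peaks, near their 38.1% share of the genome, and exons 6.49%. Intergenic sequence held 25.8% of the peaks and 54.6% of the genome. Outside promoters the median width was 836 bp in exons, 709 bp in introns and 691 bp between genes.

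A promoter peak was found at 14603 of 21938 protein-coding genes, 66.6% (interval 65.9 to 67.2). The share in the strict lists was 66.7% in replicate 1 and 66.4% in replicate 2, and 226 genes had one in a single replicate. The share followed promoter CpG content. Among genes in the lowest decile of observed over expected CpG 3.60% had a promoter peak, in the fourth 50.02%, in the fifth 84.4% and in the highest 99.5%. Olfactory receptor genes, which serve smell and have CpG-poor promoters, had one at 4 of 1092 genes (0.366%, interval 0.0999 to 0.935). This lay below the 3.60% of the lowest CpG decile, so promoter CpG content alone does not account for it. The 4, named after their values were seen, were Olfr1033, Olfr571, Olfr658 and Olfr314, each covered over at most 0.476 kb. The olfactory receptor list had a median of 0 kb, as did its random lists, so that comparison could not show a lower coverage.

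Coverage around genes of the 18 lists was set against what promoter CpG content gives. The 20 kb window also counts peaks of neighbouring genes, and gene density was not matched in this comparison. A value therefore need not be the gene's own mark: Tnnc2 had 6.22 kb and Olfr750 5.07 kb with no promoter peak. Across all protein-coding genes the median was 2.34 ± 0.0841 kb, and 24.7% of genes were at 0 kb. Of the 18 lists, 10 stood above their matched random lists, 1 below and 7 within. Those above were the 8 lists of heart cells and their support tissue, the blood cell list and the housekeeping list.

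Cardiac transcription factors carried the widest marking, with a median of 10.04 ± 0.266 kb against 3.002 kb in random lists, whose central 95% ran from 2.31 to 3.89 kb. A promoter peak was present at 25 of the 26. Hand2, a basic helix-loop-helix factor of the right ventricle, was covered over 19.7 ± 0.0361 kb of its 20 kb window, the largest value of any protein-coding gene. Nkx2-5, a homeobox factor of early heart precursors, followed with 18.6 ± 0.138 kb. The T-box factors Tbx20, Tbx5 and Tbx2, which pattern the chambers and the atrioventricular canal, had 16.8 ± 0.424, 15.1 ± 0.523 and 13.6 ± 0.0672 kb. The zinc finger factors Gata6 and Gata4 had 15.6 ± 0.0693 and 11.7 ± 0.369 kb. Mef2d, a muscle gene regulator, had 15.5 ± 0.578 kb, the Iroquois factor Irx5 14.4 ± 0.0396 kb, and Nr2f2, an atrial identity factor, 14.1 ± 0.310 kb. At the lower end stood Hopx with 5.22 ± 0.355 kb, Mef2a with 5.06 ± 0.0530 kb and Pitx2, a left-right patterning factor, with 4.32 ± 0.364 kb. Mef2c was at 0 kb around the 5′ end of its gene record in both replicates, and had a promoter peak at another of its 27 annotated start sites.

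Sarcomere and natriuretic peptide genes, the contractile and hormone genes of heart muscle cells, had a median of 7.70 ± 0.297 kb against 0.918 kb in random lists of like CpG-poor promoters. A promoter peak was present at 26 of the 27. Myh7, the slow myosin heavy chain of the embryonic ventricle, had 16.1 ± 0.220 kb, and its neighbour Myh6 on chromosome 14 had 11.6 ± 0.269 kb. Cardiac troponin I, Tnni3, had 11.96 ± 0.382 kb and the ventricular light chain Myl2 had 11.9 ± 0.153 kb. Tnni1, the slow skeletal troponin I, had 2.40 ± 0.515 kb. Myom2, an M-band protein, had 0.532 ± 0.0672 kb and no promoter peak at any annotated start site.

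Calcium handling, ion channel and conduction genes had a median of 5.96 ± 0.0417 kb against 2.43 kb, with 6.03 and 6.08 kb in replicates 1 and 2. Slc8a1, the sodium-calcium exchanger, had 12.4 ± 0.308 kb, and phospholamban, Pln, which restrains the calcium pump, had 10.6 ± 0.0368 kb. The gap junction gene Gja1 had 10.4 ± 0.113 kb, and Atp2a2, the calcium pump itself, 9.81 ± 0.244 kb. Low values were seen around the 5′ end of the gene record at Gja5, a connexin of atria and conduction fibres, with 1.92 ± 0.139 kb. The pacemaker channel gene Hcn1 had 2.60 ± 0.138 kb. The record of Gja5 is long, from 96904693 to 97077416 on chromosome 3. Other start sites of list genes were looked at only where that end had no promoter peak, so low values hold for that end only. Cardiac metabolism genes stood only just above their random lists, with 3.41 ± 0.155 kb at a percentile of 97.6. Without replicate 1 that percentile was 97.1 and without replicate 2 it was 97.4, both inside the central 95%. Ckm, muscle creatine kinase, had 6.28 ± 0.0856 kb, the nuclear receptor Esrra 6.07 ± 0.515 kb, Cpt1b, which carries fatty acids into mitochondria, 5.80 ± 0.828 kb, and aconitase Aco2 5.49 ± 0.580 kb. Ckmt2 had 0.891 ± 0.0962 kb and myoglobin, Mb, 0.421 ± 0.595 kb around the 5′ end of its gene record, with a promoter peak at another of its 6 annotated start sites.

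Signalling genes of heart development had a median of 6.35 ± 0.0912 kb against 3.09 kb in random lists. Smad6, an inhibitor of BMP signalling, had 10.7 ± 0.125 kb, the Notch ligand Jag1 10.3 ± 0.955 kb, the endothelin receptor gene Ednra 8.26 ± 0.416 kb and Bmp4 8.24 ± 0.330 kb. Nrg1, a neuregulin of the endocardium, had 2.11 ± 0.0502 kb, and Fgf10, a growth factor of the second heart field, 0 kb around the 5′ end of its gene record, with a promoter peak at another start site.

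The other cell types of the heart were marked too. Endocardial and endothelial genes had a median of 6.09 ± 0.00919 kb against 2.59 kb, with 5.97 and 5.99 kb in replicates 1 and 2. Tal1, a factor of blood and endothelium, had 15.2 ± 1.48 kb, the Notch ligand Dll4 11.9985 ± 0.161 kb, the valve regulator Nfatc1 11.5 ± 0.300 kb and the endocardial receptor gene Npr3 10.6 ± 0.0240 kb. Tal1 was covered over 16.3 kb in replicate 1 and 14.2 kb in replicate 2, while the list's median difference was 0.2465 kb. Whether blood or endothelium carried its mark was not tested. Erg had 2.12 ± 0.118 kb. Pecam1 had 0.0965 ± 0.136 kb around the 5′ end of its gene record and a promoter peak at another start site. Epicardial, valve and fibroblast genes had a median of 7.31 ± 0.398 kb against 2.29 kb, and all 19 had a promoter peak. Tbx18 and Wt1, transcription factors of the epicardium, had 12.6 ± 0.789 and 12.3 ± 0.413 kb, the receptor gene Pdgfra 12.3 ± 0.482 kb and the collagen gene Col1a1 9.68 ± 1.60 kb. The smallest were Lum with 2.38 ± 0.231 kb and Upk3b with 1.04 ± 0.247 kb. Smooth muscle and pericyte genes had 4.08 ± 0.310 kb against 1.91 kb, all 12 with a promoter peak. Their largest values were at Cspg4 (6.97 ± 0.204 kb), Pdgfrb (5.95 ± 0.134 kb), Smtn (5.12 ± 0.0389 kb) and Kcnj8 (4.78 ± 0.210 kb), and their smallest at Myh11 (1.86 ± 0.132 kb) and Mylk (1.69 ± 0.0643 kb). Over gene bodies with 5 kb flanks this list lay within its random range, at a percentile of 93.0.

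Blood cell genes had a median of 2.84 ± 1.53 kb against 0 kb in random lists of like promoter CpG content, with promoter peaks at 12 of the 20. The spread is that of the replicate difference given above. Against unmatched random lists this list lay within the central 95%, at a percentile of 80.2.

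The hepatocyte, skeletal muscle and neuronal lists all lay within their random ranges. For hepatocyte and skeletal muscle genes the lower limit was 0 kb, so these lists could not have fallen below it. Hepatocyte genes had a median of 0.323 ± 0.0325 kb (0.393 and 0.347 kb in replicates 1 and 2) against 0.702 kb, and 6 of 21 had a promoter peak. Alb and Ahsg, secreted liver proteins, were at 0 kb, while the foregut factor Foxa2 had 6.00 ± 0.0184 kb and Foxa3 2.72 ± 0.276 kb. Fgb had 2.58 ± 0.222 kb and Hnf1a 2.49 ± 0.0403 kb, both with no promoter peak. Skeletal muscle genes had 1.72 ± 0.183 kb against 1.09 kb, with promoter peaks at 7 of 20; Mylpf had 7.40 ± 0.280 kb, Tnnc2 6.22 ± 0.120 kb, Pax3 4.15 ± 0.253 kb and Acta1 4.04 ± 0.0651 kb, and the adult fast myosins Myh1 and Myh2 were at 0 kb. Neuronal genes had 2.28 ± 0.0421 kb against 2.76 kb, with promoter peaks at 18 of 22. Neurog2 had 6.67 ± 0.155 kb, Pax6 6.33 ± 0.716 kb, Dlx2 5.27 ± 0.924 kb and Ascl1 4.53 ± 0.186 kb, all developmental regulators. Phox2b had 1.31 ± 0.0283 kb, and Slc17a6, a glutamate transporter, was at 0 kb.

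Pluripotency and germ cell genes were the only list below their random range, with a median of 1.06 ± 0.0976 kb against 2.30 kb (central 95% from 1.51 to 3.46 kb). The sarcomere, blood cell, hepatocyte, skeletal muscle and olfactory receptor lists had a lower limit of 0 kb and could not fall below theirs. Dppa4 and Mael were at 0 kb, and Nanog had 1.98 ± 0.0566 kb with no promoter peak. The meiotic gene Sycp2 had 5.08 ± 0.0976 kb, also with no promoter peak, Tdgf1 2.46 ± 0.538 kb and Ddx4 2.29 ± 0.0113 kb. Against unmatched random lists the list lay within the central 95%, at a percentile of 5.16.

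Among developmental transcription factors of other organs all 28 had a promoter peak, against a mean of 26.6 in CpG-matched random lists. Their median of 3.79 ± 0.0714 kb lay within the random range of 2.503 to 4.08 kb. Otx1, a forebrain factor, had 8.44 ± 0.259 kb, Six1 5.81 ± 0.293 kb, Pax9 5.26 ± 0.626 kb and Six2, a kidney progenitor factor, 5.11 ± 0.132 kb. Otx2 had 2.17 ± 0.785 kb and Pax8, a thyroid and kidney factor, 0.918 ± 0.140 kb. Hox cluster genes had a median of 3.64 ± 0.0891 kb (3.45 and 3.58 kb in replicates 1 and 2), also within their range, with promoter peaks at 33 of 39. Hoxa2 had 16.8 ± 1.01 kb, Hoxb4 14.0 ± 1.11 kb, Hoxb3 13.8 ± 0.310 kb and Hoxa1 12.1 ± 0.649 kb, while Hoxc10 had 0.402 ± 0.00495 kb and Hoxc11 0.180 ± 0.255 kb.

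Housekeeping genes had a median of 5.21 ± 0.155 kb against 3.03 kb and promoter peaks at 25 of 26. The ribosomal protein gene Rpl13a had 10.996 ± 0.942 kb, Hmbs of haem synthesis 10.6 ± 0.499 kb, the RNA polymerase gene Polr2a 9.40 ± 0.339 kb and Chmp2a 9.27 ± 0.0198 kb, and the proteasome genes Psmb4 and Psmb2 had 2.12 ± 0.0311 and 2.09 ± 0.0997 kb. Cell cycle genes had 4.31 ± 0.168 kb, within their range, and all 18 had a promoter peak. Aurkb had 9.08 ± 0.442 kb, Ccnd2 8.76 ± 0.125 kb, Mcm2 7.65 ± 0.597 kb and Pcna 7.15 ± 0.671 kb, and Bub1 and Ccnb2 had 2.64 ± 0.00707 and 2.39 ± 0.0948 kb. Among olfactory receptor genes the largest values were 5.07 ± 0.213 kb at Olfr750 and 2.54 ± 0.132 kb at Olfr148, neither with a promoter peak.

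The 10 protein-coding genes with the largest coverage included 6 transcription factors of development, Hand2, Meis2, Nkx2-5, Tbx20, Hoxa2 and Meis1. After Hand2 came Meis2, a homeobox cofactor, with 19.3 ± 0.342 kb, then Nkx2-5, Skida1 with 17.8 ± 0.0778 kb, Bahcc1 with 17.1 ± 0.701 kb and Bcl6b with 16.8 ± 0.0417 kb. Tbx20, Hoxa2, the histone H3K4 methyltransferase gene Setd1b with 16.4 ± 0.485 kb and Meis1 with 16.3 ± 0.305 kb completed them.

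Stitching gave 47088 domains with a median width of 1.03 kb, of which 250 reached 10 kb. The widest, of 35.4 kb on chromosome 1 from 132356928 to 132392361, lay over Tmcc2. The next, of 32.9 kb on chromosome 17 from 12737620 to 12770529, covered the start of Igf2r, an imprinted receptor gene, and its antisense transcript Airn. A domain of 29.3 kb on chromosome 14 from 63227876 to 63257185 lay inside Gata4, outside the window scored around the 5′ end of that gene. Domains of 27.4 kb over Smad7, an inhibitor of TGF-beta signalling, 26.6 kb over Hand2, 25.9 kb over the RNA-binding gene Qk and 25.7 kb over Nr2f2 were also among the 10 widest, as was one of 25.1 kb over Hoxa1, Hoxa2 and Hoxa3. The others were 27.3 kb inside Ank1, the red cell ankyrin gene, and 24.97 kb over Rbm38, an RNA-binding gene. Strict peaks covered 29.3 ± 0.598 kb of the Igf2r domain and 28.4 ± 0.0686 kb of the Gata4 domain. The spread was larger over Tmcc2, at 27.0 ± 4.66 kb, and Ank1, at 21.6 ± 5.16 kb. Membership depended on the stitching gap, with 4 of these 10 among the widest when only touching peaks were joined and 5 with gaps of up to 3 kb.

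**Figure D2:**
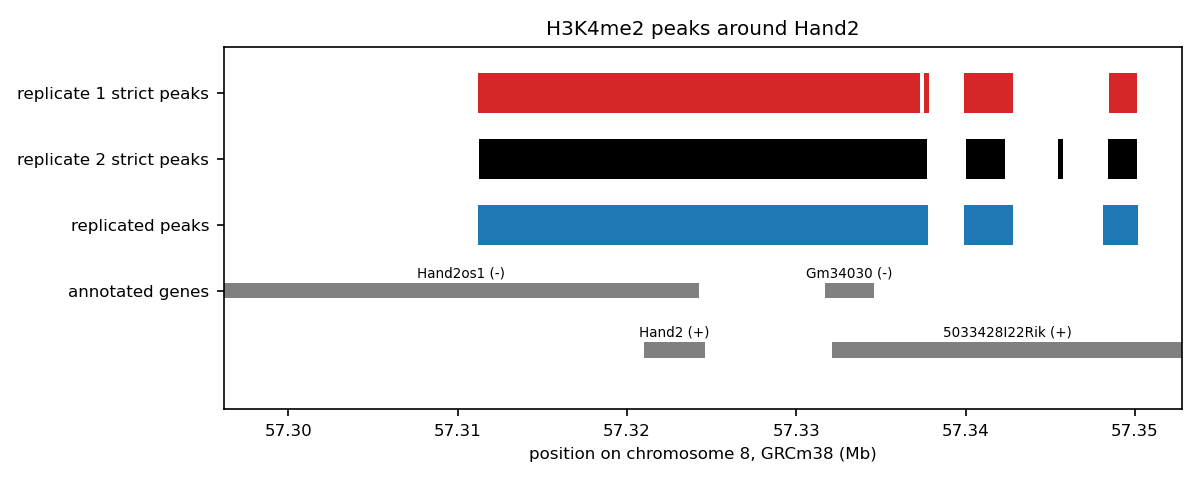
Strict peaks of replicate 1 and replicate 2, replicated peaks and annotated genes (rows, strand in brackets) around Hand2 on chromosome 8, with GRCm38 position in Mb on the x axis. One replicated peak runs from 57311200 to 57337780 and spans the whole of Hand2 and the 5′ part of its antisense neighbour Hand2os1.

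Domains of at least 10 kb held the 5′ end of 13 of 26 cardiac transcription factors (interval on the share 29.9 to 70.1%), against 1.23% of all protein-coding genes. They also held that of 5 of 27 sarcomere genes, 4 of 21 calcium and conduction genes, 4 of 20 endothelial genes, 3 of 19 epicardial, valve and fibroblast genes, 4 of 39 Hox genes and 2 of 23 signalling genes. Among the 28 factors of other organs the count was 0, and it was also 0 for cardiac metabolism, smooth muscle and pericyte, neuronal, hepatocyte, skeletal muscle, pluripotency, cell cycle and olfactory receptor genes. It was 1 of 20 for blood cell genes and 1 of 26 for housekeeping genes.

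The last comparison asks which sequence motifs mark the distal peaks. Distal peaks made up 45.7% of the replicated list, and 25025 of their windows were searched. The motif of MEF2, a factor of muscle gene enhancers, was present in 4.35% of windows against 0.849% of flanking windows, a ratio of 5.12 (interval 4.56 to 5.75). The motif of CTCF, an insulator protein, was present in 2.67% against 0.327%, a ratio of 8.16 (6.83 to 9.75). In 200 bp windows the CTCF ratio was 0.703, on the other side of 1. That window leaves out most CTCF sites near summits, with 25 within 100 bp of a summit and 728 between 100 and 300 bp. SP/KLF had a ratio of 3.47, ETS 3.06, the MYOD E-box 1.71, RFX 1.69 and TEAD, a partner of muscle and epicardial enhancers, 1.62. OCT-SOX had 2.68 from 9 windows against 6, with an interval of 0.952 to 7.52. From as few windows, its ratio was 4.55 in 200 bp windows, 5.86 against GC-matched flanks and 9 against shuffled peak sequence. The GATA motif was present in 33.0% of windows against 28.03%, a ratio of 1.18. Peak windows had a median GC content of 49.2% against 44.4% in flanks, and against GC-matched flanks the ratio of GATA was 1.58 and that of MEF2 9.21, while that of SP/KLF was 2.04. Against shuffled peak sequence MEF2 had 10.7, RFX 3.39, FOX 1.83, SP/KLF 1.56 and ETS 1.51. AP-1 sites were in 10.4% against 9.01% of windows. The HAND E-box had a ratio of 1.14, FOX 1.10, NKX2-5 and the SRF CArG box 1.05 each, T-box 0.929, HNF4 0.924, NFY 0.822 and the liver factor HNF1 0.465 from 6 windows. HNF1 had 0.875 against GC-matched flanks and 0.202 in 200 bp windows. With GC-matched flanks FOX had 1.37, NKX2-5 1.25 and the SRF CArG box 1.197. In that setting the HAND E-box had 1.02, HNF4 0.937, NFY 0.904 and T-box 0.881. Shuffled peak sequence gave 0.847 for NKX2-5 and 0.737 for the SRF CArG box. Whether NKX2-5 and SRF motifs were enriched therefore depended on the background.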

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

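In the replicated list 13 peaks lay on sequences outside the assembled chromosomes. Such peaks entered the counts and overlaps of the peak lists, but not the comparisons with annotated genes, chromosomes or motifs. The deposited replicate lists held 12 and 14 such peaks.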

How the results depend on the processing

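Of 144 alternative values of the gene list comparison, 119 kept their side of the limits. The cardiac transcription factor, sarcomere, calcium and conduction, signalling, endothelial, epicardial and housekeeping lists stood above their random lists in each of them. The cause of the changes below was not tested, apart from that of the CTCF ratio, for which site positions around summits are given. The metabolism list no longer stood apart with all deposited peaks (percentile 97.4), with the replicated list (97.4), with random lists unmatched (95.4) or matched on gene length (96.0), or without either replicate (97.1 to 97.4). Smooth muscle genes no longer did so over gene bodies with flanks (93.0). With random lists unmatched or matched on length, blood cell genes (80.2 and 90.7) and pluripotency genes (5.16 and 7.98) lay within. In the same settings these lists newly stood apart: hepatocyte (1.24 and 2.26), other-organ factors (99.6 and 99.7), cell cycle (99.8 and 99.8), Hox (99.8 and 99.9) and olfactory receptor genes (percentile 0 in both). Over gene bodies hepatocyte (2.5), cell cycle (99.5), Hox (99.4) and olfactory receptor genes (percentile 0) did so too.

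Shares of peaks in promoters, exons, introns and between genes were 37.5, 5.09, 32.5 and 24.9% with a 2.5 kb promoter window. They were 35.1, 4.81, 35.5 and 24.6% with start sites of all genes, and 24.6, 6.44, 42.3 and 26.7% in the pooled list. With −log10 q of at least 5 the first 3 were 32.2, 6.54 and 35.7%. In 1 replicate's strict list alone the 4 shares ranged from 27.7 to 30.0%, 6.51 to 6.56%, 39.1 to 40.5% and 24.5 to 25.2%. Genes with a promoter peak made up 68.7% with the 2.5 kb window, 70.1% with any annotated start site, 67.4% with the pooled list and 60.9% when at least 50% of the window had to be covered. The share of pooled peaks in the replicated list was 77.5% at −log10 q of at least 2. Rank agreement fell to a rho of 0.864 with missing peaks at a signal of 0. Of the 10 widest domains, 4 were among the widest with touching peaks only and 5 with 3 kb gaps. The promoter share of shared peaks was 40.7% with a 2.5 kb window, 34.1% when 50% of a peak had to be covered, 31.6% with all deposited peaks and 38.1% at −log10 q of at least 5. That of peaks in 1 replicate only was 18.5% with the 2.5 kb window. Of 108 alternative motif ratios, 7 crossed 1. In 200 bp windows these were CTCF at 0.703, the SRF CArG box at 0.980 and NKX2-5 just below 1, and against shuffled sequence HNF1 at 1.5, SRF at 0.737, NKX2-5 at 0.847 and the HAND E-box at 0.981. Read depth is not given in the sources used here, so which weak peaks it leaves out is unknown.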

Other observations

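Tests on blood list differences, on the CpG content and gene density of chromosome X and on the factors of other organs were chosen after those patterns had been seen, and the genes and motif positions named here likewise. The hypotheses on Hox clusters, distal peaks and MEF2 sites were set before their tests were run, but were not among the comparisons first planned. Hox genes were covered unevenly along their clusters. Genes of paralogue groups 1 to 5, which act in the hindbrain and anterior trunk, had a median of 7.33 kb, groups 6 to 9 had 3.90 kb and groups 10 to 13, which pattern the posterior body, 1.69 kb. These medians pool 4 clusters that differed. The A cluster fell from 8.65 to 4.84 and 1.69 kb and B from 11.3 to 4.41 and 0.920 kb. In C the anterior genes, at 1.55 kb, lay below the middle ones at 3.33 kb, with 0.843 kb at the posterior end, and D was nearly flat at 4.08, 4.00 and 2.96 kb. The hypothesis that coverage falls along the clusters was tested over all 39 genes, which are neighbours and not independent. The test used the same covered lengths as those given above for the most and least covered Hox genes, so it is not independent of them. Spearman's rho of group number and covered length was -0.589, with -0.621 in replicate 1 and -0.559 in replicate 2. It was -0.873 in the A cluster, -0.503 in B, -0.367 in C and -0.243 in D.

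Distal peaks were dense around cardiac transcription factors, though not around them alone. A hypothesis that they gather there was tested against random lists matched on gene density. The window of 100 kb includes the 10 kb either side of the TSS scored above, where this list already stood apart, so the results are not independent. The median was 5.5 distal peaks within 100 kb of the TSS against 2, a percentile of 100. Prdm16 had 12, Myocd 11, and Gata4 and Gata6 10 each. Calcium and conduction genes had a median of 5 (percentile 99.98), endothelial genes 4.5 (99.96), signalling genes 4 (99.4) and blood cell genes 3 (99.5), each above the upper limit of its random lists. Sarcomere (97.9), metabolism (97.3), skeletal muscle (96.4) and cell cycle genes (95.4), all at a median of 3, and Hox genes, at 2 (95.8), equalled theirs. The epicardial, valve and fibroblast list (66) and the smooth muscle and pericyte list (67.15), each at a median of 2, lay within their random ranges. A second hypothesis, that MEF2 sites are more frequent in distal peaks near sarcomere genes, stayed open: 7 of 97 such peaks had the motif, a ratio of 1.66 to other distal peaks with an interval of 0.813 to 3.40.

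Motifs differed in where they sat around distal summits. CTCF sites numbered 25 within 100 bp of a summit and 728 between 100 and 300 bp, or 0.833 and 12.1 times the density found 700 to 1000 bp away. MEF2 sites had 3.24 and 4.91 times that density. TEAD sites, at 1.70 and 1.63, and SP/KLF sites, at 3.25 and 2.87, were as dense at the summit as beside it or denser.

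All 13 red cell members of the blood list were more covered in replicate 1, with a median difference of 2.87 kb, and its 7 white cell and platelet members went the same way by 0.044 kb (percentile 97.7 of matched random lists, 4 higher in replicate 1 and 0 in replicate 2). The blood list's median difference lay at percentile 100 of random lists matched on covered length, but the list was singled out by this same difference. That percentile therefore does not weigh against wider calling throughout replicate 1, whose strict peaks covered 72.3 Mb against 67.1 Mb. A larger share of erythroid cells in the tissue of replicate 1 may account for the red cell difference. Of 15 erythroid genes outside the lists, which include the broadly used Tfrc and Epb41, 14 were higher in replicate 1, by a median of 1.45 kb. Their percentile was 100, also with Hbq1a, left out after its values were seen because its window overlaps that of an alpha-globin gene of the blood list. These genes argue against calls wider by a like amount at all genes of like covered length. Peak strength was not matched, so wider calling at some kinds of peak stays open. The share of peaks with a GATA motif, which a blood cell source could raise, was 1.04 times as high in distal peaks of replicate 1 only as in those of replicate 2 only, with an interval of 0.989 to 1.10, which leaves a wider blood cell source open. White cells cannot be judged: 12 macrophage genes, at percentile 38.8, had medians of only 0.236 and 0.280 kb in replicates 1 and 2, and the white cell and platelet members 0.637 and 0.513 kb.

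Chromosome X had 8.05 ± 0.219 strict peaks per Mb (SD, n = 2), against 19.5 to 38.5 on autosomes, and 1.965 distal replicated peaks per Mb against at least 7.62. Gene density alone is argued against, as X has 5.54 protein-coding genes per Mb and chromosome 12, with 5.35, had 20.8 peaks per Mb. Promoter CpG content alone is argued against too: 51.7% of X genes had a promoter peak against 59.7% (57.5 to 61.8) in CpG-matched autosomal sets, a percentile of 0. Fewer active copies of X per cell in these pooled male and female embryos remain open. Median promoter signal on X was 0.607 ± 0.0309 times that of CpG-matched autosomal genes, but the scale of the signal is not stated, so this ratio does not decide. Repeat content and unique alignment of reads were not examined, and no group separates the sexes.

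The promoter peaks at all 28 developmental factors of other organs could follow from promoter CpG content, since 12.5% of CpG-matched random lists also had one at every gene. Cells of other organs in the dissected tissue remain open: of 36 CpG-poor neuronal, hepatocyte and skeletal muscle genes 8 had a promoter peak against 10.6 in matched random lists, a percentile of 15.9. That is under the percentile of 50 first set for excluding them, but inside the spread of the random lists, so that limit was too loose to exclude them.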
